A study of Danio rerio with 6 samples.

How the data were processed

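Single-cell RNA was measured in pools of zebrafish embryos of 2 genotypes at 3 ages. Per the labels, embryos were stripped of yolk, dissociated with trypsin and run with the 10x 3' CellPlex protocol, which marks each sample with a multiplexing oligo. The deposited matrices hold counts: UMIs per gene and per multiplexing tag for each cell barcode, with no normalization. The file headers and the submitters' processing notes name Cell Ranger 7.1.0, and the notes also name Seurat and the GRCz11 genome build without stating the role of either. Each of the 6 matrices has 32520 genes and 12 tags, of which the authors' tag key assigns 6 to samples. The barcodes had been called as cells and assigned to a tag before deposit. The 2 matrices of an age share 0 barcodes, and matrices of different ages share between 3 and 19 (12 pairs).

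The labels give 2 records per age, with the library types GEX (gene expression) and CMO (multiplexing oligo), and name both genotypes for each record, in the genotype field as a knockdown and in the titles as a homozygous mutant. Genotype was therefore taken from the authors' tag key together with the tag UMIs of the cells. By this reading each GEX record is the wild-type matrix of its age and each CMO record the knockout matrix, so every ratio of knockout over wild type is also a ratio of CMO over GEX record. Both kinds of record hold gene counts. The assigned wild-type tag gave 93.1%, 94.4% and 94.7% of tag UMIs in the wild-type matrices at 12, 24 and 36 hpf, and the knockout tag gave 96.0%, 90.5% and 92.0% in the knockout matrices. Cells led by another tag numbered 11, 0 and 15 in wild type and 0, 9 and 0 in the knockout. The tag of the other genotype at the same age gave 4.01% to 9.49% of tag UMIs, and no further tag gave more than 0.0233%. Beside the 0 barcodes shared within an age, this argues that both genotypes of an age were run together and divided by tag. All columns of per-sample values were mapped to a group (0 unmapped).

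For the whole-matrix comparison, UMIs were summed over all deposited barcodes of a matrix and scaled to CPM of all gene UMIs. Gene IDs that share a symbol were summed. With 1 matrix per group no test, standard error or count of changed genes was computed. Ratios carry exact conditional binomial intervals, counts exact Poisson intervals and shares exact Clopper-Pearson intervals, all at 95%. A count of 0 was taken to allow 3 counts. Ratios against 0 UMIs are given as at least that against the floor.

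Gene lists and cell type marker lists were fixed before the data were examined, as were the comparisons, the rule for named genes and the first set of alternatives. There were 13 gene lists and 22 marker lists. A list member needed 10 UMIs over the 2 matrices of an age. The median log2 ratio of a list used 0.5 UMIs added per gene and was ranked among 10000 random lists of the same size, matched on expression in 20 bins. Of 173 list results, 5 had a member at 0, and setting such members at their bound moved 1 median by over 0.1 and reversed 0. The named-gene rule took genes with at least 20 CPM in a matrix of the age. It named the 10 higher and 10 lower genes with the largest smallest ratio over the 3 ages and counting intervals that exclude 1, and the 5 highest and 5 lowest at each age. It also took hamp, every measured hemoglobin and heme synthesis gene, and up to 4 members of each other list. Some genes that this rule takes are not reported here. In erythroid-like cells and between ages the minimum was 50 CPM, with 5 genes per direction. Genes between ages were ranked by the smaller of their wild-type and knockout changes. Genes with clone names were passed over for the next named gene. Genes outside this rule were picked after their values were seen: acsl4a, fbxl5, fth1a, fth1b, gpx4b, slc40a1, tfr1a, hmox1a at 24 hpf and mitfa at 36 hpf, and gpx4a, pmaip1 and rhd in erythroid-like cells. So were the genes that name single clusters.

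Cells with at least 200 detected genes and at most 20% mitochondrial UMIs (13 genes) were kept. Over 20% mitochondrial UMIs were found in 0, 66 and 112 wild-type cells and in 0, 37 and 114 knockout cells. Both matrices of an age were clustered together in scanpy 1.11.5 with 2000 variable genes, 30 principal components, 20 neighbours and Leiden clustering (leidenalg 0.10.2, python-igraph 0.11.9) at resolution 1. The genes of the hemoglobin, heme synthesis, iron handling and ferroptosis lists were left out of the variable genes. The Scrublet doublet caller, run with an expected rate of 0.06, did not work on these data: its automatic threshold called 0, 2 and 1 wild-type cells at 12, 24 and 36 hpf and 0 knockout cells at each age. Removing the called cells left 5195, 5571 and 5225 wild-type and 2976, 6462 and 8098 knockout cells for the shares of classes. A cluster took a class name when at least 3 markers were 3-fold higher in it and found in 15% of its cells, with a marker in its 10 leading genes, or 5 markers otherwise. A cluster stayed unnamed when another class had more markers among its 10 leading genes, even with enough markers. A 24 hpf cluster of 75 wild-type and 81 knockout cells with 12 markers is 1 example. Clusters with a median depth under 0.333 of the matrix median stayed unnamed if no marker was among their leading genes. This scoring rule was written after the clusters were seen. It leaves unnamed a 24 hpf cluster of 289 wild-type (5.19%) and 346 knockout cells (5.35%). A class was compared within cells only with at least 30 cells in both matrices.

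Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9. The first set of alternatives was median-of-ratios scaling, scaling without hemoglobin genes, subtraction of free hemoglobin RNA measured in retina-like cells, means of per-cell CPM, and clusters weighted to the same share. Others were filtered barcodes only, Leiden resolutions of 0.6 and 1.6, clustering with all variable genes, doublet calls kept, a stricter filter of 1000 genes and 5% mitochondrial UMIs, and cells thinned to 1500 UMIs. The retina-like class was chosen as the measure of free RNA after the clusters were seen. Alternatives added after the data were seen left out barcodes over 50000 UMIs, the top 5% of doublet scores, cells led by another tag, or 1 cluster of the 12 hpf pair, or added to a class the unnamed clusters with at least 3 of its markers among their leading genes. Barcodes over 50000 UMIs held 6.97%, 6.00% and 20.3% of wild-type UMIs and 11.6%, 5.02% and 10.4% of knockout UMIs.

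The comparison was tested on simulated data with the depth of each pair. Of 200 genes planted at 1.5, 2, 4 and 8-fold, 100% had the planted direction at every age, and 86% to 100% of intervals per fold and age held the true value. Lists of unchanged genes fell outside the central 95% of random lists in 4.25%, 3.50% and 4.25% of cases at 12, 24 and 36 hpf. These simulated counts were independent draws from a profile pooled over the pair, and the lists held random genes of at least 20 CPM. Differences in cell mixture and genes that move together were not simulated, so percentiles of the real lists are not calibrated by this. The test of neighbouring genes put a planted block at percentile 99.9. Gene neighbourhoods used gene names, chromosomes and start positions of the GRCz12tu reference table. Reads were not used here, so near-identical gene copies could not be recounted and the edited hamp sequence was not examined.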

Results

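The data are single-cell RNA counts from whole zebrafish embryos at 12, 24 and 36 hours post fertilization (hpf), taken from wild-type embryos and from embryos in which hamp was knocked out with CRISPR/Cas9. hamp encodes hepcidin, a peptide hormone that limits iron export from cells through ferroportin. Each sample pooled 50 embryos, and the cells of the 2 genotypes carried different multiplexing tags. There were 6 groups of 1 sample each, so there were no replicates, and every difference reported here is between single samples. The wild-type matrices held 5195, 5639 and 5338 cells at 12, 24 and 36 hpf, with 70000963, 71707524 and 63042075 gene UMIs (unique molecular identifiers). The knockout matrices held 2976, 6499 and 8212 cells, with 60596159, 75362882 and 72958965 gene UMIs. The median UMIs per cell were 6424, 10334 and 7185 in wild type and 20797, 9865 and 5904 in the knockout. All intervals are 95% and cover counting error only. Ratios are knockout over wild type on the log2 scale, from UMIs scaled by the library total (CPM), unless stated otherwise.

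The targeted gene itself gave very few UMIs. At 12 hpf hamp had 0 UMIs in both matrices, which allows a hamp UMI in up to 0.0577% of wild-type and 0.101% of knockout cells and sets no limit on cells that express it. At 24 hpf it had 1 UMI in wild type and 0 in the knockout, where up to 0.0462% of cells could still carry a UMI. At 36 hpf it had 133 UMIs in wild type (interval 111 to 158) and 3 in the knockout (0.619 to 8.77), a log2 ratio of -5.68. Of the wild-type UMIs, 109 came from 1 pronephros-like cell, and 2 remained without the barcodes over 50000 UMIs. These counts are too few to check the genotype of either matrix. A 3' tag that lies outside a deleted part of the gene would in any case be counted in both genotypes.

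The series title links loss of hamp to hemoglobin synthesis, so hemoglobin RNA was compared first. Knockout embryos had more hemoglobin RNA than wild type at 24 hpf and less at 36 hpf. The share of erythroid-like cells moved the same way, while the hemoglobin share inside those cells differed little. Part of the 36 hpf difference lay outside erythroid-like cells. These cells held 1130849 of 1370349 hemoglobin UMIs in wild type and 1035719 of 1133934 in the knockout. Wild-type endothelial-like cells of that age had 4.42% hemoglobin UMIs, against 0.1% in the knockout. The heme synthesis list had medians above 0 in knockout erythroid-like cells at both ages, with 0 genes 2-fold higher. hbbe1.1 and hbbe1.2 were lower in those cells, while the sum of the 3 near-identical hbbe1 copies differed little and the split between them is uncertain.

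Over the whole matrix, hemoglobin genes made up 1.27% of wild-type and 1.86% of knockout UMIs at 24 hpf, a log2 ratio of 0.56 (0.55 to 0.56). At 36 hpf they made up 2.17% and 1.55%, a log2 ratio of -0.48 (-0.49 to -0.48). At 12 hpf hemoglobin was near its floor, at 0.00102% and 0.000876% of UMIs (log2 ratio -0.22, -0.39 to -0.06). Erythroid-like cells were 92 of 5571 wild-type cells at 24 hpf, or 1.65% (1.33 to 2.02), and 178 of 6462 knockout cells, or 2.75% (2.37 to 3.18). At 36 hpf they were 85 of 5225 cells, or 1.63% (1.3 to 2.01), against 89 of 8098, or 1.1% (0.884 to 1.35). The ratio of shares was 1.67 (1.29 to 2.17) at 24 hpf and 0.676 (0.496 to 0.920) at 36 hpf. No cluster could be named erythroid at 12 hpf. Inside erythroid-like cells, hemoglobin made up 30.2% and 31.0% of UMIs at 24 hpf (log2 ratio 0.04) and 58.8% and 57.3% at 36 hpf (-0.04). When every cluster was weighted to the same share in both matrices, the whole-matrix log2 ratio was -0.0769 at 24 hpf and 0.00369 at 36 hpf. In erythroid-like cells found by clustering on all variable genes, the 36 hpf ratio was 0.0915. Retina-like cells, which do not make hemoglobin, carried 0.0959% and 0.106% hemoglobin UMIs at 24 hpf and 0.0742% and 0.0732% at 36 hpf.

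**Figure D1:**
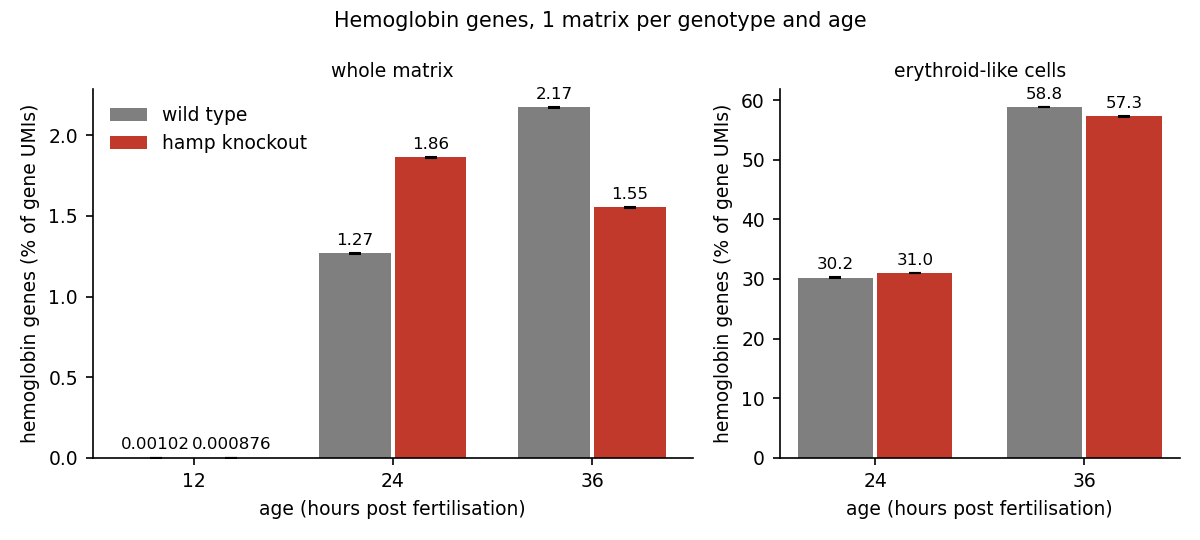
Hemoglobin genes as a percent of all gene UMIs, in the whole matrix and in erythroid-like cells, for wild type (grey bars) and the hamp knockout (red bars), 1 sample per bar. The whole-matrix share is 1.27% against 1.86% at 24 hpf and 2.17% against 1.55% at 36 hpf, while the erythroid-like shares differ by a log2 ratio of 0.04 and -0.04.

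The embryonic alpha-globins followed the whole-matrix pattern. At 24 and 36 hpf the log2 ratios were 0.60 and -0.59 for hbae1.1, 0.71 and -0.38 for hbae1.3, 0.44 and -0.57 for hbae3, and 0.32 and -0.28 for hbae5. The embryonic beta-globin hbbe3 had ratios of 0.50 and -0.50, and hbbe1.3 had 0.80 and -0.31. By contrast, hbbe1.1 was lower at both ages (-2.10 and -3.08), as were hbbe1.2 (-0.29 and -1.71) and hbbe2 (-0.14 and -0.86). At 12 hpf hbbe1.2 had a ratio of 0.84 and hbbe1.3 of -1.35. The adult-type globins were rare. hbaa1 had 12 UMIs in wild type and 359 in the knockout at 24 hpf, and 12 and 71 at 36 hpf. At 24 hpf hbaa2 had 6 and 70 UMIs, hbba2 had 3 and 49 (3.96, 2.33 to 6.28), and hbba1 had 1 and 55 (5.71, 3.17 to 11.04). Of the 24 hpf knockout hbaa1 UMIs, 239 came from 1 erythroid-like cell.

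Within erythroid-like cells, hbbe1.1 went from 3604 CPM in wild type to 495 in the knockout at 24 hpf (log2 ratio -2.86, -2.93 to -2.79) and from 7525 to 988 CPM at 36 hpf (-2.93, -3.00 to -2.86). hbbe1.2 was lower by a log2 ratio of -0.85 at 24 hpf and -1.27 at 36 hpf. hbbe1.3, the most abundant of these copies, was higher, at 0.30 and 0.14. The 3 copies are nearly identical and share reads, so the split between them is uncertain. Their sum was 118092 CPM in wild type and 125374 in the knockout at 24 hpf, and 288330 and 284562 CPM at 36 hpf. The other embryonic globins differed less than hbbe1.1: hbae1.1 had 0.09 and -0.16, hbae1.3 0.21 and 0.07, hbae3 -0.09 and -0.13, hbae5 -0.20 and 0.25, hbbe2 -0.69 and -0.41, and hbbe3 -0.03 and -0.07. The rare adult-type hbaa1 was at 5.38 at 24 hpf, where 1 knockout cell held 239 of its UMIs. Of 13 hemoglobin genes measured there, 4 were at least 2-fold higher and 1 lower. In single cells, hbbe1.2 was over 8% of the hbbe1 UMIs in 78 of 92 wild-type cells at 24 hpf, or 84.8% (75.8 to 91.4), and in 90 of 178 knockout cells, or 50.6% (43.0 to 58.1). At 36 hpf the shares were 58.8% (47.6 to 69.4) and 32.6% (23.0 to 43.3). Most other cells were under 1%. Over 24% were 41 wild-type and 8 knockout cells at 24 hpf, and 25 and 3 at 36 hpf. hbbe1.1 was over 2% of the hbbe1 UMIs in 68.5% of wild-type and 1.69% of knockout cells at 24 hpf, and in 50.6% and 1.12% at 36 hpf.

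**Figure D2:**
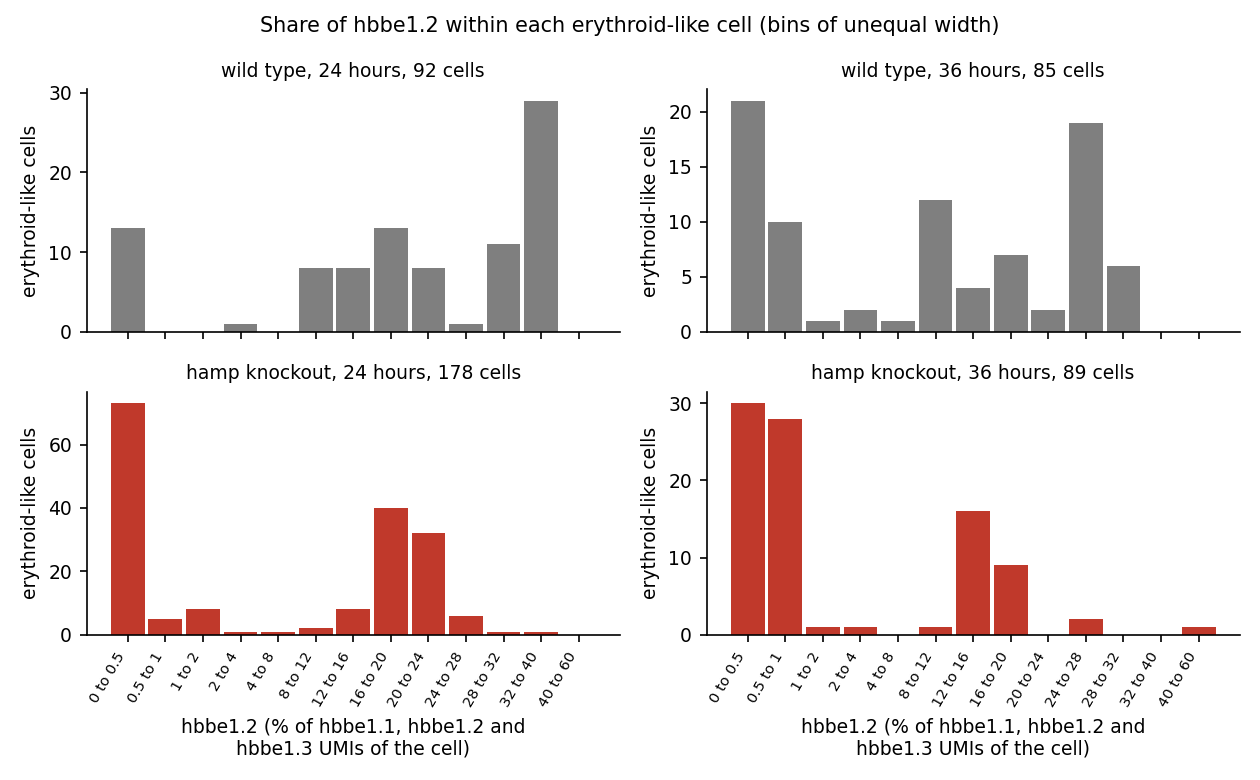
Histograms of hbbe1.2 as a percent of the UMIs of the 3 hbbe1 copies in each erythroid-like cell, 1 panel per genotype and age, with bins of unequal width. Cells form a group under 1% and a group over 8%, and the group over 8% holds 84.8% of wild-type and 50.6% of knockout cells at 24 hpf. That wild-type group is itself split, with 8 cells at 20% to 24%, 1 at 24% to 28% and 11 at 28% to 32%. Over 24% were 41 wild-type and 8 knockout cells.

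Heme synthesis starts with the aminolevulinate synthases and ends with ferrochelatase (fech), which inserts iron. Over the whole matrix the heme synthesis and mitochondrial iron import list had a median log2 ratio of -0.01 at 12 hpf, 0.48 at 24 hpf and -0.08 at 36 hpf. The 24 hpf median was 0.10 with clusters weighted to the same share. The erythroid synthase alas2 had ratios of 0.86 at 24 hpf and -0.11 at 36 hpf, and the housekeeping synthase alas1 had -0.03 and 0.43. The middle enzymes at 24 hpf were alad at 0.47, hmbsa at 0.12, hmbsb at 0.89, uros at 0.27, urod at 0.57, cpox at 0.74 and ppox at 0.79. fech was at 0.57 at 24 hpf and 0.14 at 36 hpf. Mitochondrial transporters at 24 hpf included slc25a38a, the glycine carrier, at 0.93, slc25a38b at 0.50, the iron importer slc25a37 (mitoferrin) at 0.23, slc25a39 at 0.18, abcb10 at 0.56, tmem14ca at 0.52 and tmem14cb at -0.53. The iron-sulfur cluster genes glrx5 and fxn were at 0.31 and 0.04. In erythroid-like cells the list median was 0.35 at 24 hpf, with intervals above 0 for 13 of 18 genes and below 0 for 1, and 0.31 at 36 hpf, with intervals above 0 for 8 of 18. There alas2 had ratios of 0.39 and 0.32, hmbsb 0.51 and 0.38, cpox 0.38 and 0.13, ppox 0.40 and 0.51, urod 0.20 and 0.44, alad 0.27 and 0.26, fech 0.41 and 0.45, and slc25a37 0.19 and 0.65.

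The erythroid transcription factor list had a median of 0.31 in the 24 hpf knockout matrix, where the share of erythroid-like cells was 1.67 times that of wild type. Of its 19 genes 12 had intervals above 0 and 1 below. At least 2-fold higher were 3: gfi1aa at 2.29, the repressor gfi1b at 1.23 and the globin activator klf1 at 1.05. nfe2 followed at 0.99. Its median was 0.20 at 12 hpf and 0.00 at 36 hpf, and 0.38 and 0.30 in erythroid-like cells at 24 and 36 hpf. The erythrocyte membrane and carbonic anhydrase list had medians of -0.14, 0.45 and -0.13 at the 3 ages. Its 24 hpf members included the skeleton gene add2 at 0.95, the red cell carbonic anhydrase cahz at 0.70 and epb41b at 0.61. The Rh blood group gene rhd was lower at 24 and 36 hpf, at -0.79 and -1.51. In erythroid-like cells rhd had 108 CPM in wild type and 38.7 in the knockout at 24 hpf (-1.48, -1.77 to -1.19), and a log2 ratio of -1.32 at 36 hpf. That membrane list had medians of 0.14 and 0.16 in these cells.

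By the size rule, the genes most above wild type in 24 hpf knockout erythroid-like cells were hbaa1, the glycerol-3-phosphate dehydrogenase gpd1b (2.46), the histone gene hist1h2a6 (1.98), the translation factor eif3hb (1.66) and the mitochondrial calcium uniporter subunit smdt1b (1.63). The most below were the lipoprotein gene apoc1 (-3.28), hist1h2a10 (-3.05), hbbe1.1, dnase1l4.1 (-2.83) and the Notch target her15.1 (-2.40). apoc1 also leads a 24 hpf paraxial cluster, and the paraxial mesoderm list was at -1.50 in these erythroid-like cells, with 7 of 10 genes at least 2-fold lower. Endothelial markers there were at 1.14 (4 of 8 at least 2-fold higher) and myeloid markers at 2.33 (3 of 3). At 36 hpf the highest were igfbp1a (2.49), which binds insulin-like growth factor, the copper chaperone cox17 (1.55), the folate enzyme mthfd2 (1.48), susd1 (1.32) and hist1h2a6 (1.32). The lowest were the splicing factor rbfox1 (-3.25), hbbe1.1, the dipeptidase pepd (-2.31), the catenin ctnna2 (-2.23) and her15.1 (-2.19). Neuron markers were lower in these cells too (median -1.07, 10 of 20 at least 2-fold lower), as were neural progenitor markers (-0.65). The apoptosis gene pmaip1 (noxa) was at 3.71 and 2.41 in these cells, from 9 and 5 wild-type UMIs.

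The series title also names ferroptosis, an iron-dependent death by lipid peroxidation. Of the ferroptosis list, gpx4a, a glutathione peroxidase that reduces lipid peroxides, was more than 2-fold higher in the knockout at every age. Most other members differed by less than 2-fold, its paralog gpx4b among them. At 24 hpf the list member sat1a.1 differed by more than gpx4a, in the other direction. The iron handling list had medians of at most 0.16 over the whole matrix, and of 0.14 and 0.36 in erythroid-like cells at 24 and 36 hpf. The heat shock and unfolded protein lists were highest at 36 hpf, when skeletal muscle markers were higher too (1.11), and the p53, hypoxia and glutathione lists were highest at 12 hpf.

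gpx4a had log2 ratios of 2.73, 1.44 and 1.82 at 12, 24 and 36 hpf, from 5.13 to 34.1 CPM at 12 hpf, 9.29 to 25.1 CPM at 24 hpf and 6.55 to 23.2 CPM at 36 hpf. Its ratio in erythroid-like cells was 2.86 at 24 hpf and 1.94 at 36 hpf. gpx4b was at 0.05, 0.04 and -0.10. The ferroptosis list had medians of 0.12, 0.13 and 0.17, above 95.2%, 99.4% and nearly all of 10000 random lists matched on expression, as a description of these matrices. At 12 hpf the cystine transporter slc7a11 was at 1.90, from 9 wild-type UMIs, and the glutathione synthetase gss at 1.41. At 24 hpf the polyamine enzyme sat1a.1, which promotes ferroptosis, was at -2.29. The prostaglandin synthase ptgs2b was at 1.07 and 1.25 at 24 and 36 hpf, heme oxygenase hmox1a at 0.73 and 0.87, and ferritin fth1b at 0.73 and 0.70. acsl4a, which loads membranes with oxidizable fatty acids, was lower at all 3 ages (-0.35, -0.28 and -0.33). The iron handling list had medians of 0.12, 0.16 and -0.01, above 88.2%, 98.5% and 50.4% of random lists. At 12 hpf blvrb, which acts on heme breakdown products, was at 2.12, and the hepcidin inducer bmp6 at 1.28. Transferrin tfa was at 0.89 at 12 hpf and -2.44 at 24 hpf. The heme exporter flvcr1 was at -0.92 and -1.16 at 24 and 36 hpf, the iron sensor fbxl5 at 0.83 at 24 hpf, and the ferrireductase steap3 at -1.02 at 36 hpf. The hepcidin target ferroportin, slc40a1, was at -0.07 and -0.15, and the erythroid transferrin receptor tfr1a at 0.71 and 0.52. In erythroid-like cells tfr1a was at 0.33 and 0.89 and ferritin fth1a at 0.24 and 0.44. The iron handling medians there were 0.14 and 0.36 and the ferroptosis medians 0.16 and 0.32.

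The glutathione and antioxidant list had medians of 0.21, 0.02 and 0.05, the first above 99.9% of random lists. Its 12 hpf members were led by catalase (cat, 1.61), gsto2 (1.25), thioredoxin (txn, 0.94) and the mitochondrial superoxide dismutase sod2 (0.81). The p53 and apoptosis list had medians of 0.35, 0.11 and 0.23, the first above 99.98%. pmaip1 was at 1.27 and casp3b at -1.15 at 12 hpf, and baxb at 0.87 and casp8 at 0.73 at 36 hpf. The unfolded protein and integrated stress response list had medians of 0.12, 0.03 and 0.24, with the chaperone dnajb9b at 0.89, sesn2 at 0.85 and atf3 at 0.63 at 36 hpf. The heat shock and immediate early list had medians of -0.03, 0.09 and 0.38. At 36 hpf 5 of its 31 genes were at least 2-fold higher, among them hsp90aa1.1 (1.46), hsp70.2 (1.42), hsp70.3 (1.34) and hsp70.1 (1.12). Averaging per-cell CPM gave this list 0.16 at 36 hpf. In erythroid-like cells its median was 0.49 at 36 hpf and became -0.0312 when clustering used all variable genes. The hypoxia and glycolysis list had medians of 0.29 (above 99.81%), 0.07 and 0.23, with hexokinase hk2 at 1.36, ndrg1a at 1.15, igfbp1b at 1.08 and gapdh at 1.03 at 36 hpf. The cell cycle list had small medians (0.13, 0.06 and -0.08), with the replication helicase gene mcm7 at 0.61 at 12 hpf. The first was above 99.6% of random lists, with 25 of 31 intervals above 0 and 2 below. At 36 hpf 6 intervals were above 0 and 19 below. The BMP pathway, which induces hepcidin, had medians of 0.11, 0.04 and 0.06, with the antagonist nog3 at 1.44 at 12 hpf and bmp4 and bmp2a at 0.80 at 36 hpf.

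**Figure D3:**
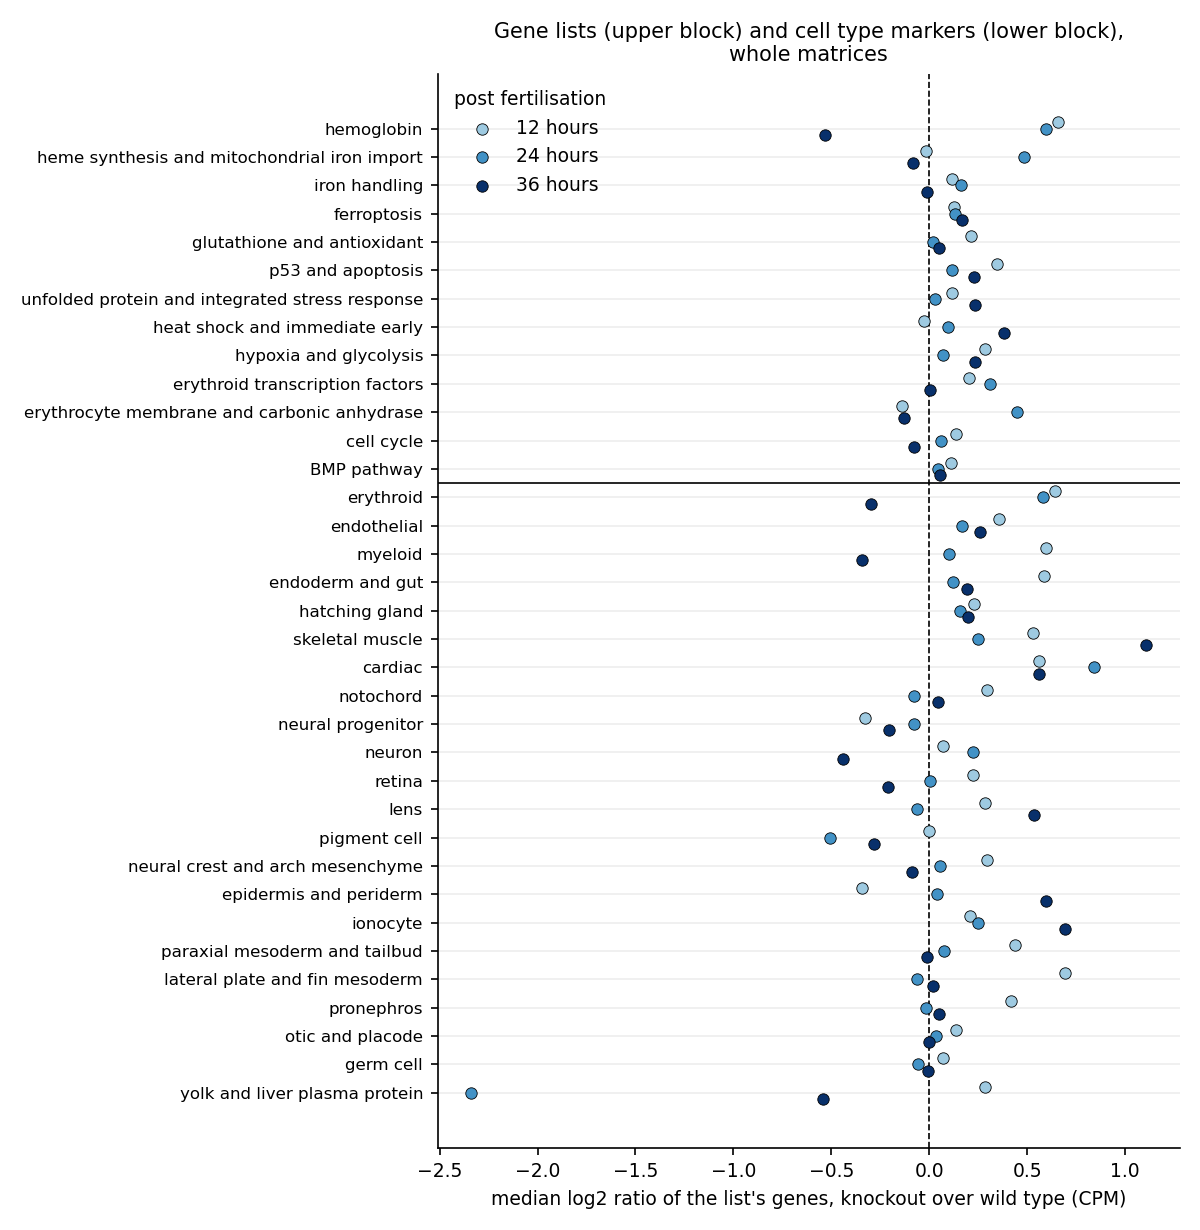
Median log2 ratio, knockout over wild type, of each gene list (upper block, 13 lists) and each cell type marker list (lower block, 22 lists) over the whole matrix, coloured by age. The hemoglobin list stands at 0.60 and -0.53 at 24 and 36 hpf, and the yolk and liver plasma protein list at -2.34 at 24 hpf.

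The knockout and wild-type matrices also held different mixtures of cell types. At 12 hpf lateral plate and endodermal classes took larger shares of the knockout, and neural progenitors a smaller one, while the paraxial mesoderm ratio depended on which clusters were counted. At 24 hpf epidermis-like cells were fewer and hatching gland-like cells more frequent in the knockout. At 36 hpf neural crest and neuron classes were smaller, as was the pigment class, although its clusters were of opposite balance. The largest cluster of that age, unnamed but with hatching gland genes, took a larger share of the knockout. Unnamed clusters held 69.7% of wild-type and 62.9% of knockout cells at 12 hpf, 38.2% and 36.5% at 24 hpf, and 29.8% and 35.6% at 36 hpf. With 1 sample per group, a cluster held mostly by 1 matrix is a feature of that embryo pool and its preparation as much as of its genotype.

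At 12 hpf paraxial mesoderm and tailbud cells were 6.16% of wild-type and 10.7% of knockout cells, a ratio of 1.73 (1.48 to 2.03). This class joined clusters of opposite balance: a muscle-forming cluster with ttn.1 and myod1 held 200 wild-type and 87 knockout cells, a tailbud cluster with msgn1 and her1 held 93 and 155, and a cluster with nog1 and meox1 held 27 and 76. The largest cluster of this age, unnamed by the scoring rule but led by tbx6, msgn1 and tcf15, held 980 wild-type (18.9%) and 400 knockout cells (13.4%). With it the class held 1300 and 718 cells, a share ratio of 0.964 (0.879 to 1.06). Lateral plate and fin mesoderm was 3.6% and 6.12% (ratio 1.70, 1.38 to 2.09), and endoderm and gut 1.62% and 2.76% (1.70, 1.24 to 2.34). Neural progenitors were 6.64% and 4.74% (0.713, 0.582 to 0.870), from 1 cluster led by the eye field genes rx3 and six3b, while notochord was 3.62% and 4.57%, most of it from a cluster led by nkx2.4b that has nkx2.9 and nkx2.2b beside shha and shhb, which floor plate shares (115 and 78 cells), and epidermis 8.32% and 7.73%. The knockout cells of this age had a median of 20797 UMIs against 6424, a gap that can set whether a cell falls in a named class. At 24 hpf epidermis and periderm was 9.91% and 6.99% (0.706, 0.622 to 0.801), although 1 of its clusters had 0.951% and 1.15%, and neurons 10.4% and 11.8% (1.13, 1.02 to 1.26). Hatching gland was 5.42% and 7.41% (1.37, 1.18 to 1.58), named from 3 markers in cells with medians of 4385 and 3425 UMIs, against 10334 and 9865 in the matrices. Endothelial cells (1.67% and 1.78%), skeletal muscle (8.29% and 8.16%) and pigment cells (2.24% and 2.06%) were close. At 36 hpf neural crest and arch mesenchyme was 9.24% and 6.36% (0.688, 0.606 to 0.781), pigment cells 2.85% and 1.85% (0.650, 0.514 to 0.820), and neurons 23.1% and 18.7% (0.810, 0.750 to 0.874). Of the pigment clusters, the one led by tyrp1b had 1.13% and 0.593%, the one with gch2 1.15% and 0.469%, with medians of 11704.5 and 3630.5 UMIs, and the one with rlbp1b 0.574% and 0.790%. Neuron-like cells had a median of 5605.5 UMIs in wild type and 2958.5 in the knockout. Neural progenitors were 10.8% and 12.8% (1.19, 1.07 to 1.32), from 1 cluster led by en2b and with pax7a, so they are another group of cells than at 12 hpf. Retina was 4.63% and 6.0% (1.3, 1.11 to 1.52), and endothelial cells 1.47% in both. The largest 36 hpf cluster, unnamed by the scoring rule, held 725 wild-type (13.9%) and 1500 knockout cells (18.5%), with a median of 2214 UMIs. Its leading genes included the hatching gland markers ctslb, he1.1 and he1.2, and no hatching gland class was named at this age. Its larger share in the knockout lowers the other knockout shares.

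**Figure D4:**
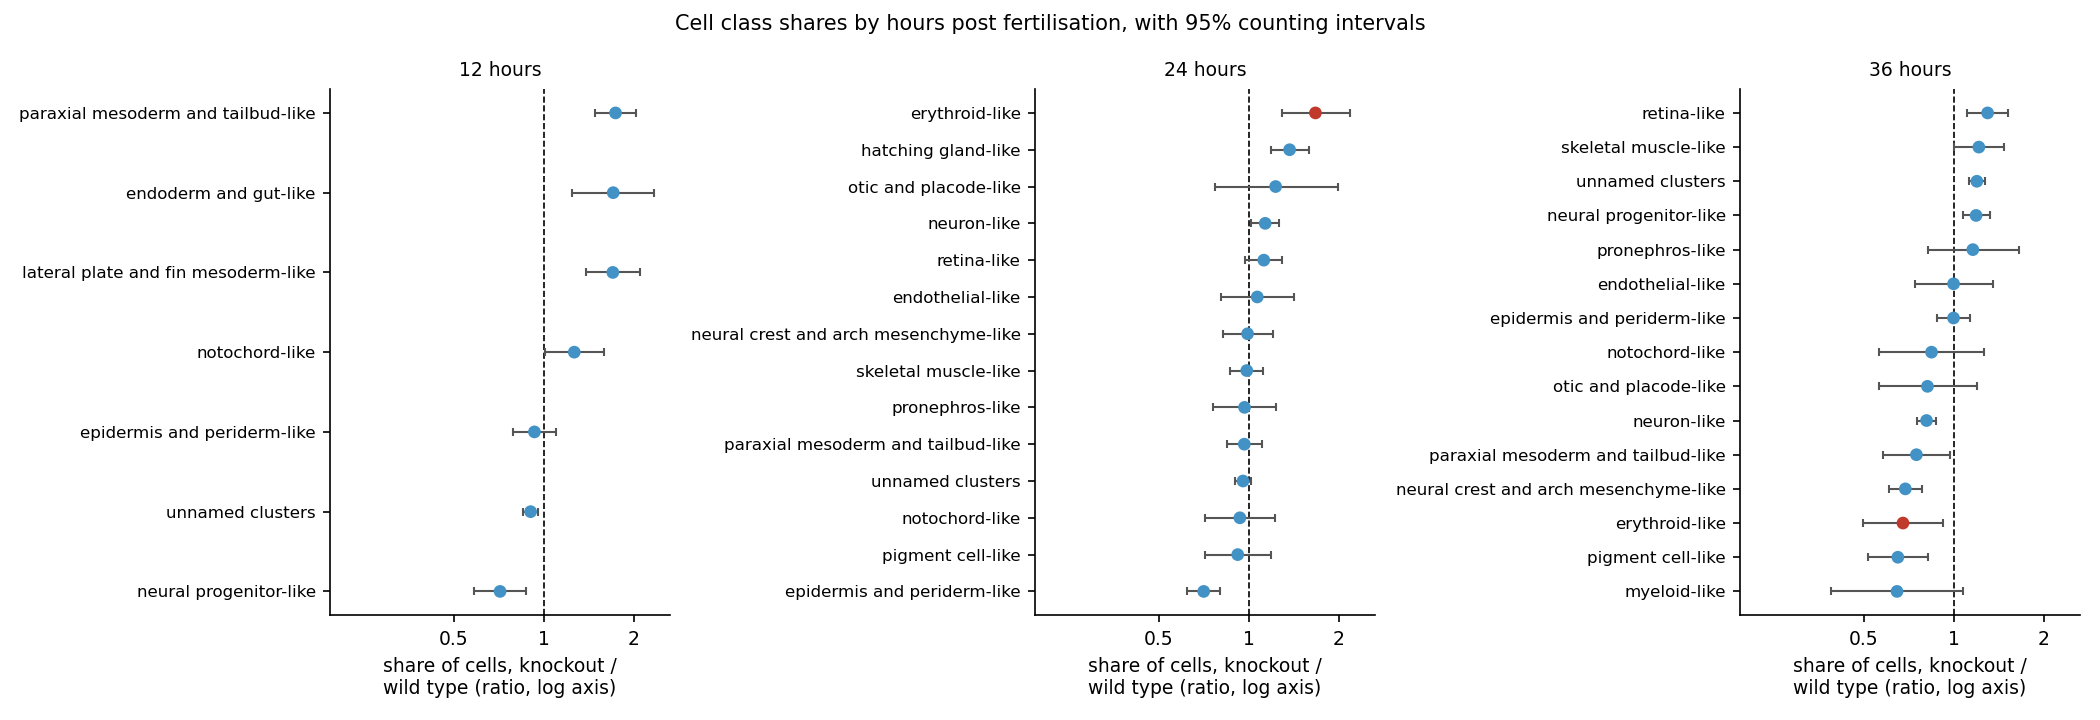
Ratio of the share of cells, knockout over wild type, for each named class with at least 30 cells in both matrices, on a log axis with 95% counting intervals and erythroid-like cells in red. The erythroid-like ratio is 1.67 at 24 hpf and 0.676 at 36 hpf, and the paraxial mesoderm ratio at 12 hpf is 1.73 for the named clusters alone.

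Marker lists over the whole matrix add genes to these shares. The erythroid list had medians of 0.64, 0.58 and -0.30 at 12, 24 and 36 hpf, with hemgn at -1.01 and blf at -0.44 at 36 hpf. The endothelial list was at 0.35, 0.17 and 0.26, led at 12 hpf by the angioblast genes tie1 (2.62) and etv2 (2.24). The myeloid list was at 0.60, 0.10 and -0.34. With clusters weighted to the same share, both the erythroid and the myeloid median were at 0.16 at 36 hpf. At 24 hpf the neutrophil genes mpx (3.2) and lyz (2.96) were higher in the knockout, and at 36 hpf npsn (-1.03) and the macrophage genes mpeg1.1 (-0.70) and csf1ra (-0.65) were lower. The 24 hpf myeloid class held only 8 wild-type and 7 knockout cells, and lyz had 136 and 1113 UMIs. The 24 hpf ratios may therefore rest on few cells. Skeletal muscle markers were at 0.53, 0.25 and 1.11, with 18 of 21 at least 2-fold higher at 36 hpf, including actin acta1a (1.28), myod1 (1.26), creatine kinase ckmb (1.25) and troponin tnnt3a (1.21). The 36 hpf muscle median was 0.65 without barcodes over 50000 UMIs and 0.49 as a mean of per-cell CPM. Cardiac markers were at 0.56, 0.84 and 0.56, with the troponins tnnc1a at 1.18 and tnni1b at 1.00 and the atrial myosin myh6 at -1.28 at 24 hpf. Yolk and liver plasma protein genes were at 0.29, -2.34 and -0.54. At 24 hpf 11 of 16 were at least 2-fold lower, with apoa4a at -4.02, afp4 at -2.79, serpina1l at -2.74 and apoa2 at -2.60. As a mean of per-cell CPM, that median was -0.29.

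Neural lists differed by age. Neural progenitor markers were at -0.33, -0.08 and -0.20, with her15.1 at -2.69, the hindbrain gene egr2b at -1.65 and her4.1 at -1.08 at 12 hpf. Neuron markers were at 0.07, 0.23 and -0.44, led at 36 hpf by onecut1 and rtn1b (both -0.56). As means of per-cell CPM, the 36 hpf medians were -0.0117 for neurons, 0.0117 for neural progenitors and 0.0753 for retina. Retina markers were at 0.22, 0.00 and -0.21, lens at 0.28, -0.06 and 0.53, and otic and placode at 0.13, 0.03 and 0.00. Pigment cell markers were at 0.00, -0.51 and -0.28, and the 24 hpf median was 0.00835 as a mean of per-cell CPM. The melanocyte regulator mitfa was at -1.17 and -1.01 at 24 and 36 hpf, the iridophore kinase ltk at -1.16 and -1.14, and gpnmb at -1.48 at both ages. With clusters weighted to the same share, the 36 hpf pigment median was 0.0793. Neural crest and arch mesenchyme markers were at 0.30, 0.05 and -0.09. Epidermis and periderm markers were at -0.34, 0.04 and 0.60, with the hemidesmosome collagen col17a1a at 1.35, krt92 at 1.04 and cldne at 0.89 at 36 hpf. Ionocyte markers were at 0.21, 0.25 and 0.69, led by atp1b1b (1.45) and the calcium channel trpv6 (1.02) at 36 hpf. Paraxial mesoderm markers were at 0.44, 0.07 and -0.01, with mespaa at 1.01 and tbx16 at 0.94 at 12 hpf. Lateral plate markers were at 0.69, -0.06 and 0.02, endoderm and gut at 0.58, 0.12 and 0.19, and hatching gland at 0.23, 0.16 and 0.20. Notochord (0.29, -0.08 and 0.04), pronephros (0.41, -0.02 and 0.05) and germ cell markers (0.07, -0.06 and 0.00) were near 0 from 24 hpf on.

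Some genes differed in the same direction at all 3 ages, across large changes of embryonic stage. They are given as single genes, and no shared function was tested. Genes known only by clone names ranked among them and were passed over for the next named gene.

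The 10 named genes higher at 12, 24 and 36 hpf were gpx4a, hist1h2a6 (1.12, 2.23 and 1.49), the lysosomal protease ctsba (1.12, 1.95 and 1.55), hk2 (1.1, 1.12 and 1.36), smdt1b (2.10, 1.35 and 1.04), the axonal adhesion gene cntnap2a (1.90, 1.74 and 0.97), the glutathione transferase gsta.1 (1.05, 1.09 and 0.82), the tubulin deglutamylase agbl4 (2.32, 1.65 and 0.81), the selenoprotein selenow2a (0.72, 0.87 and 0.87) and the actin nucleator subunit arpc5a (0.69, 0.78 and 0.61). The 10 lower were her15.1 (-2.69, -2.60 and -2.20), the mitochondrial outer membrane gene fundc2 (-2.45, -2.15 and -2.04), the nucleotide hydrolase dnph1 (-1.78, -1.64 and -1.40), her12 (-1.84, -1.80 and -1.31), hist1h2a10 (-1.21, -1.41 and -1.27), hist1h2a3 (-0.76, -1.29 and -1.29), the Hedgehog co-receptor gas1b (-0.76, -0.84 and -0.82), the respiratory complex gene higd2a (-0.93, -0.72 and -0.73), the FGF signalling inhibitor spry4 (-0.85, -0.87 and -0.69) and il1rapl1a (-3.32, -0.78 and -0.65). her15.1 has a near-identical copy, her15.2, that went the other way (0.44, 1.16 and 1.08), and the pair summed to -0.70, -0.13 and -0.02. The hist1h2a10 and hist1h2a6 pair summed to 0.47, 0.79 and 0.50, so single members of these families are uncertain. Over 4187 genes with at least 20 CPM at all ages, 1692 (40.4%) had the same direction at all 3 ages, where independent signs would give 25%. Across genes, which are not independent replicates, Pearson's r between ages was 0.593 (12 and 24 hpf), 0.447 (12 and 36 hpf) and 0.686 (24 and 36 hpf), and Spearman's rho was 0.437, 0.272 and 0.457.

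**Figure D5:**
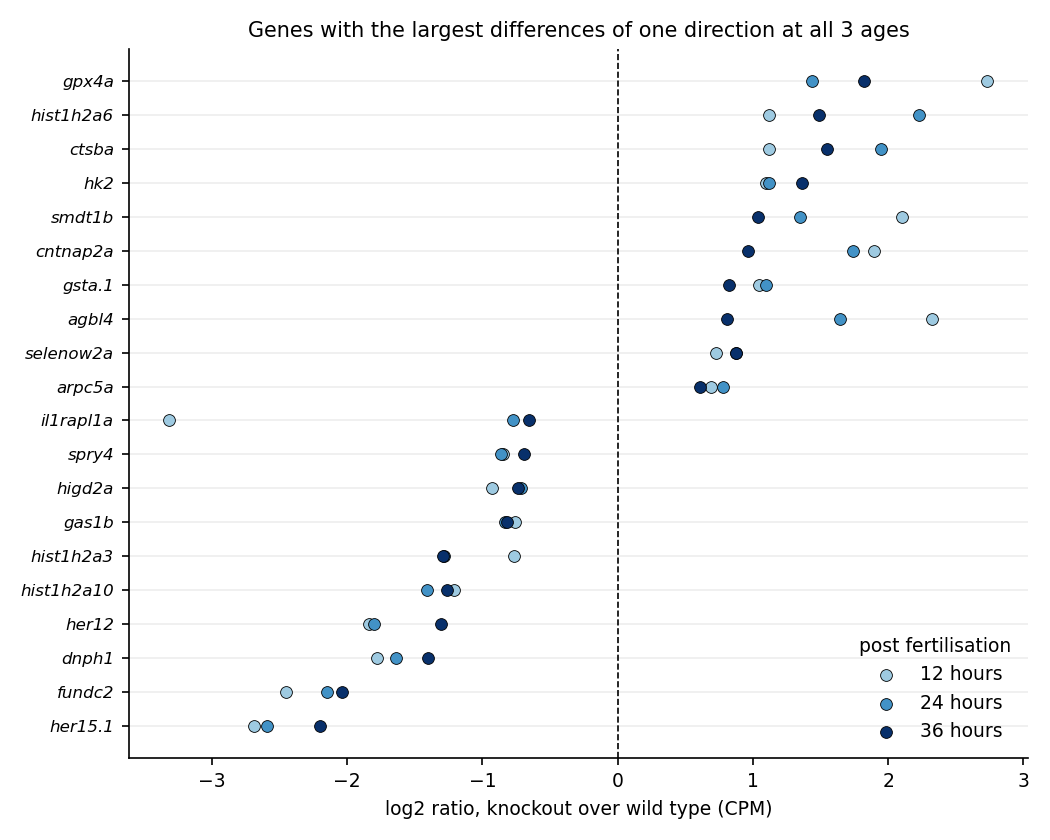
Log2 ratios, knockout over wild type, of the 20 named genes that differ in the same direction at 12, 24 and 36 hpf, 1 point per age. gpx4a stands at 2.73, 1.44 and 1.82, and her15.1 at -2.69, -2.60 and -2.20.

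At each single age the size rule named some of these genes again and others besides. The highest at 12 hpf were the secreted Wnt-related gene dkk3a (3.81), gpx4a, agbl4, the connexin cx28.1 (2.24) and smdt1b. The lowest were the muscle actin-binding gene xirp2a (-3.73), the RNA-binding gene celf2 (-3.36), il1rapl1a, her15.1 and sema5a (-2.66). At 24 hpf the phosphate transporter slc34a1a (4.01) and the immunoproteasome subunit psmb10 (3.1) led hist1h2a6, ctsba and cntnap2a. The lowest were the antifreeze-like plasma gene afp4, apoa2, her15.1, the alcohol dehydrogenase adh8b (-2.38) and apoa1b (-2.34). At 36 hpf the sodium pump subunit atp1a1a.3 (5.11) was highest, then slc34a1a (3.47), the cadherin cdh18a (2.68), the small heat shock gene hspb9 (2.19) and gpx4a. The lowest were hbbe1.1, somatostatin sst1.2 (-2.40), her15.1, fundc2 and adh8b (-1.98).

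Age was the other factor of the design, and the rule for the genes named for it fixed the same direction in both genotypes. These genes rank highest by the smaller of the wild-type and knockout changes and are given as single genes. Summed hemoglobin was higher at 36 than at 24 hpf in wild type and lower in the knockout.

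At 24 over 12 hpf hbbe3 was higher by 15.33 in wild type and 14.74 in the knockout. The troponin tnnt2c was higher by 14.48 (12.00 to 19.78) and 14.31 (11.83 to 19.62), from 1 UMI at 12 hpf in each. The fast muscle light chain mylpfa was higher by 13.65 in wild type and 14.12 (12.57 to 16.39) in the knockout. The myosins myl1 and myhz1.3 were higher by 15.18 (12.71 to 20.49) and 14.56 (12.08 to 19.86) in wild type and by at least 13.64 and 12.99 in the knockout, where they had 0 UMIs at 12 hpf. The lowest were nnr (-10.07 in wild type and -10.13 in the knockout), the eye regulator six7 (-10.38 and -8.91), cdx1a (-6.64 and -7.28), s100a1 (-7.51 and -6.22) and the pluripotency factor pou5f3 (-5.83 and -6.35). At 36 over 24 hpf the actinodin genes of the fin fold were higher, and2 by 6.12 and 6.60 and and1 by 4.59 and 4.74. The parvalbumin pvalb5 (5.86 and 4.76), lysozyme lyz (8.01 and 4.58) and keratin krtt1c19e (4.41 and 4.49) were also higher. apoc1 was lower (-3.66 and -3.34), as were efemp2a (-2.22 and -2.34), tnnt2c (-2.93 and -2.19), the cytoglobin cygb1 (-2.36 and -2.12) and hsp90aa1.1 (-3.29 and -2.04). Summed hemoglobin was higher at 24 than at 12 hpf by 10.28 in wild type and 11.05 in the knockout. At 36 over 24 hpf it was higher by 0.78 in wild type, and its log2 ratio was -0.26 in the knockout.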

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

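The tests of low depth in the 12 hpf cluster, of a hemoglobin variant between embryos, and of a decrease of hbbe1.1 or hbbe1.2 shared by every knockout cell were chosen only after the result was seen. So were the comparison of the 3-age genes with other genes, the medians of cells with an hbbe1.2 share over 8%, and the rule that early embryo members going both ways by 2-fold leave the first test undecided. The count of cells under 80% of tag UMIs and the resampling of cells were added after it as well.

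Several results pointed in opposite directions at different ages, and with 1 sample per group none of these differences between ages was tested. Summed hemoglobin had log2 ratios of -0.22, 0.56 and -0.48 at 12, 24 and 36 hpf, and the hemoglobin list had medians of 0.60 and -0.53 at the later ages. Its 12 hpf median of 0.66 is within counting error, with 1 of 11 intervals above 0 and 1 below. The erythroid-like share had ratios of 1.67 and 0.676 at 24 and 36 hpf, and the erythroid marker list had medians of 0.64, 0.58 and -0.30 over the 3 ages. Neurons had share ratios of 1.13 and 0.810 and list medians of 0.23 and -0.44 at 24 and 36 hpf. Neural progenitor shares had ratios of 0.713 at 12 hpf and 1.19 at 36 hpf, from clusters of unlike cells (eye field genes in the first, en2b and pax7a in the second), and paraxial mesoderm and tailbud shares 1.73 and 0.749. The paraxial clusters were also unlike, with msgn1 and her1 or ttn.1 and myod1 among the genes at 12 hpf, and vwde, fmoda and col6a2 leading at 36 hpf. With the unnamed 12 hpf cluster that paraxial genes lead, the ratio of 1.73 was 0.964. The epidermis and periderm list had medians of -0.34 at 12 hpf and 0.60 at 36 hpf. A slower or faster embryo pool at a given age, a difference in dissociation and the genotype remain open for all of these.

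Tags that the authors' key assigns to no sample also gave UMIs, more than the 3 that a count of 0 allows. The wild-type matrices held 39, 8493 and 1948 such UMIs at 12, 24 and 36 hpf, and the knockout matrices 106, 1769 and 2585. They were at most 0.0255% of tag UMIs and led 0 cells.

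The first pattern weighed is a 12 hpf cluster of 9 wild-type cells (0.173%) and 357 knockout cells (12.0%), with pou5f3 (1.70), h1m (1.46) and thy1 (2.13) above the other knockout cells. Cells of an earlier stage stay open: the early embryo list had a median of 0.10, but its members went both ways (slbp2 2.18, ndr2 -3.48), so a low median excludes nothing, and regional and segmentation genes were lower (median -2.66, 15 of 18 at least 2-fold lower). Low depth is argued against by a median depth 1.33 times that of the knockout matrix. For the deposited cells, droplets that mix genotypes are argued against by 97.46% of tag UMIs from the knockout tag, against 96.7% in other knockout cells. Under 80% were 1.68% of the cluster's knockout cells, against 10.3% of the others. Mixed droplets set aside before deposit cannot be seen. Cells marked with the wrong tag would show the same shares, so tag UMIs cannot decide on them. After thinning to equal depth, 68.3% of the cluster's knockout cells still fell together, in a cluster of 18 wild-type and 292 knockout cells. Cells marked with the wrong tag, droplets with several knockout cells, a feature of that embryo pool or its preparation and a cell state set by the genotype stay open, and the data may hold any of them.

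The second pattern is the set of 45 genes with a log2 ratio of at least 0.5 in the same direction at all 3 ages, 21 higher and 24 lower, among 4187 genes. For the 39 members matched to the GRCz12tu table, a haplotype that acts on genes near hamp is argued against. Of these, 0 lay among the 100 nearest genes or on the chromosome of hamp. The percentile of that window, 23.3 of 1531 windows, decides nothing. Members were 0.975% of the 3999 matched genes, so windows without a member are common. Unmatched members and effects on distant genes stay open. Different mixtures of cell types are argued against, because equal weights for the clusters left the ratios at 1.00 times their size. In 1403 of 1445 values over 33 sets of a class and an age, or 97.1%, the direction was that of the whole matrix, and of all other cells taken alone. Other genes with as large a ratio at an age reached 86.7%, so this test could hardly exclude anything. A variant of the line that acts in every cell type and an effect of hamp loss on the whole body cannot be told apart. Free RNA shared by all droplets would reach both genotypes of an age if they were run together, as their tags argue.

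The third pattern is the lower hbbe1.1 and hbbe1.2 in knockout erythroid-like cells. A decrease of hbbe1.2 in every knockout cell stays open: 44.6% (119 of 267) had an hbbe1.2 share over 8%, but their median share was 19.6% against 28.6% in wild type at 24 hpf and 15.6% against 23.1% at 36 hpf. Those wild-type medians mix cells on both sides of 24%, with 41 of 92 cells over it at 24 hpf and 25 of 85 at 36 hpf. In the knockout 8 of 178 and 3 of 89 cells were over it. A decrease of hbbe1.1 in every knockout cell, with 1.5% (4 of 267) over 2%, and a hemoglobin variant that some embryos of a pool carry, with 3.83% of all erythroid-like cells (17 of 444) between 1% and 8% hbbe1.2, stay open too, because these cuts were set on the groups of cells already seen. Knockout cells with low hbbe1.2 gained 1.40 hbbe1.3 UMIs per hbbe1.2 UMI lost at 24 hpf (1.16 to 1.65 over resampled cells) and 1.19 at 36 hpf (0.721 to 1.73). Reads moved between copies give at most 1 only if reads that fit several copies were counted alike in both groups of cells. That could not be checked, so a gain over 1 excludes nothing. These explanations and an effect of hamp loss on the copies cannot be told apart.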

How the results depend on the processing

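The alternatives that left out barcodes over 50000 UMIs, the top 5% of doublet scores, cells led by another tag or the 12 hpf knockout cluster, or that added unnamed clusters to a class, were chosen only after the data were seen. No paired analysis was possible because each group had 1 sample and its cells came from pooled embryos. Of the values that answer a comparison, 253 were labelled as within their counting interval, 45 as moved beyond it and 3 as reversed. Of the others, 1729 were labelled as within it, 200 as moved and 9 as reversed. For lists, the median half-width of the members' intervals was used, which is not an interval of the list median. A list median labelled as within it is therefore not shown to be stable. Not every change of sign was labelled as reversed. The 36 hpf heme synthesis median went from -0.08 to 0.10 with clusters weighted to the same share and was labelled as moved. All 440 values of the 10 top-ranked 3-age genes per direction, clone names included, kept their direction. These genes were picked for large ratios, and the named genes ranked below them were not rerun. The erythroid-like share ratio stayed within its interval at both ages under every clustering tried. With UMIs this deep, counting intervals of summed hemoglobin are narrower than the effect of most choices. Depth limits hamp, the globins with few UMIs and all hemoglobin at 12 hpf. For each value given next, the cause was not tested.

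With clusters weighted to the same share, summed hemoglobin was at -0.48 at 12 hpf, reversed to -0.0769 at 24 hpf and reversed to 0.00369 at 36 hpf. The 24 hpf hemoglobin list reversed to -0.0243, and heme synthesis was at 0.10 at 24 hpf. At 36 hpf heme synthesis changed sign, from -0.08 to 0.10. At 36 hpf the erythroid list reversed to 0.16, the myeloid list to 0.16 and the pigment list to 0.0793, and muscle was at 0.82, neuron at -0.30 and epidermis at 0.43. As means of per-cell CPM, summed hemoglobin was at 0.48 at 24 hpf and -0.49 at 36 hpf. At 24 hpf heme synthesis was at 0.32, the yolk list at -0.29, and the pigment list reversed to 0.00835. At 36 hpf heat shock was at 0.16, muscle at 0.49, neuron at -0.0117 and epidermis at 0.30, while neural progenitor reversed to 0.0117 and retina to 0.0753.

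With median-of-ratios scaling, summed hemoglobin was at 0.53 at 24 hpf and -0.43 at 36 hpf, and at 0.0204 and -0.0806 in erythroid-like cells. At 36 hpf heat shock was at 0.44, muscle at 1.16 and epidermis at 0.66. Between ages, hemoglobin at 24 over 12 hpf was at 10.61 in wild type and 11.42 in the knockout, and at 36 over 24 hpf at 0.90 and -0.0792. Scaling without hemoglobin genes gave 0.0514 and -0.0930 in erythroid-like cells. Filtered barcodes gave -0.49 for summed hemoglobin at 36 hpf, and 0.79 and -0.25 at 36 over 24 hpf in wild type and knockout.

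Without barcodes over 50000 UMIs, summed hemoglobin was at 0.60 and -0.46 at 24 and 36 hpf, and at 0.00682 and -0.10 in erythroid-like cells. At 36 hpf muscle was at 0.65, neuron at -0.34 and epidermis at 0.50, and wild type kept 2 hamp UMIs. Without the top 5% of doublet scores, summed hemoglobin was at 0.49 and -0.53, and at 0.0525 and -0.0486 in erythroid-like cells. At 36 hpf heat shock was then at 0.30 and muscle at 1.06. Clustering with all variable genes, which brought the compared genes into the clusters, put erythroid-like hemoglobin at 0.13 at 24 hpf, reversed it to 0.0915 at 36 hpf and reversed the 36 hpf erythroid-like heat shock list to -0.0312. With unnamed clusters led by markers of a class added to it, the log2 ratio of the 12 hpf paraxial mesoderm share reversed to -0.0527.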

Other observations

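The lists also followed embryonic age within each genotype. At 24 over 12 hpf the skeletal muscle markers had medians of 9.25 in wild type and 9.46 in the knockout, the neuron markers 4.52 and 4.81, the pigment markers 4.46 and 4.34 and the endothelial markers 4.01 and 3.75. Heme synthesis was at 1.38 and 1.61, and heat shock genes at 2.88 and 2.99. Paraxial mesoderm and tailbud markers were lower at 24 hpf (-1.68 and -2.32), as were germ cell markers (-3.13 and -3.39), and the cell cycle list was at -0.52 and -0.61. Yolk and liver plasma protein genes went opposite ways, at 1.95 in wild type and -1.15 in the knockout.

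At 36 over 24 hpf myeloid markers had medians of 1.54 and 1.48, pigment markers 1.39 and 1.31, and lens markers -2.47 and -1.83. Muscle markers were at 0.83 in wild type and 1.72 in the knockout, neuron markers at 0.89 and 0.22, and epidermis markers at 0.29 and 0.84. Hemoglobin genes were at 0.70 and -0.88, hatching gland markers at 0.11 and -1.15, and yolk and liver plasma protein genes at -0.86 and 0.42. Whether the genotypes differ in these age effects was not tested.

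In erythroid-like cells, lists not covered with the hemoglobin comparison had small medians at 24 and 36 hpf: glutathione and antioxidant 0.04 and 0.13, unfolded protein response 0.05 and -0.03, hypoxia and glycolysis -0.04 and 0.03, cell cycle 0.07 and -0.12. The p53 and apoptosis list was at 0.30 and 0.27, and the BMP pathway at -0.55 and -0.48. Neuron markers there were at 0.03 and -1.07, and neural progenitor markers at -0.49 and -0.65. In wild type at 36 hpf, hemoglobin was 4.42% of UMIs in endothelial-like, 2.21% in pronephros-like and 1.53% in pigment-like cells, against 0.1%, 0.0704% and 0.114% in the knockout and 0.0742% in wild-type retina-like cells. Other erythroid markers went with it: the erythroid list was at -4.17 in endothelial 36 hpf cells (10 of 11 at least 2-fold lower), -3.79 in pronephros 36 hpf cells and -2.51 in pigment cell 36 hpf cells, so the erythroid RNA in these wild-type clusters is more than hemoglobin alone. At 24 hpf hemoglobin went both ways among classes. It was 0.656% in wild-type and 0.118% in knockout pigment-like cells, and 0.115% and 1.07% in otic and placode-like cells.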
